A study of Danio rerio with 20 samples.

How the data were processed

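RNA of the brain was sequenced in 20 libraries from male zebrafish (Danio rerio), all with the strain label AB JxTu. The libraries form 4 groups of 5: fish of 1 year or 3 years, kept without exercise or swum in a swim tunnel, a chamber in which a fish swims against a water current. The length of the exercise, the interval before sampling, the time of day and any sequencing batch are not given in the sources used here. Replicates were numbered in order of accession, so the numbers only name libraries and pair none across groups. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples.

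Per the labels' protocols, libraries were made with the TruSeq RNA v2 kit, which does not mark strand, so reads from a gene and an overlapping antisense gene cannot be told apart. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and the genome build GRCz10, without roles or settings. The authors deposited a table of whole-number read counts for 32105 Ensembl gene identifiers, which was used for all main tests, and a table of RPKM values for the same genes. How the authors' counting treated reads shared by near-identical gene copies is not given in the sources used here. Values of paralogs and of multigene families, such as the major histocompatibility, immunoglobulin-like, globin and ribosomal protein genes, are therefore uncertain.

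The deposited RPKM values were checked against the counts. Among 10136 genes with over 200 counts in every library, the gene length implied by a gene's RPKM and count varied between libraries with a median CV of 13.8% when each library's own total was used as the divisor. With the 20 library totals applied in turn down the list of genes, the median CV was 0.00217%. By that reading, 5.00% of the deposited RPKM values were divided by their own library's total, and the total used lay between 0.676 and 1.48 times the own total. The RPKM table served only for alternatives, and RPKM values were also recomputed from the counts, the implied lengths and each library's own total.

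Gene symbols came from a reference table that pairs Ensembl identifiers with symbols and matched 26269 of the identifiers. Of these, 11881 have an upper-case, human-style symbol and 4301 share their symbol with another identifier; a shared symbol is given with its identifier. No genome sequence was used here, so no coordinates are given. There were 34 gene lists, written before the data were examined, as were the designs and the rule for named genes: 25 of brain cell types, pathways and stress responses, and 9 of other cell types that dissected tissue could hold. Of 975 symbols on the lists, 883 matched an identifier; 264 list genes were matched through a family symbol without its zebrafish copy letter, so they may be another copy of the intended gene.

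Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 21148, libraries were scaled with TMM, and a quasi-likelihood F-test was run on a mean per group over all 20 libraries, with robust dispersions. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 6 comparisons were exercise at 1 year, exercise at 3 years, the difference between these exercise effects, exercise averaged over both ages, age without exercise and age with exercise. Every adjusted p given for a gene is from this edgeR test unless another tool is named. Errors of log2 fold changes are standard errors derived from the fold change and the F statistic. Levels are normalised counts (CPM) on TMM-scaled library sizes, as mean ± SD with n = 5.

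Genes named in the text were chosen by a rule. Among genes with a proper symbol, an adjusted p below 0.05 and at least 1 CPM on average in a compared group, the 10 largest fold changes in each direction were eligible, with up to 4 called members of each list. With fewer than 10 calls, the 10 genes with the smallest p were given as values. A set chosen for its place in the exercise or ageing literature was always computed (bdnf, igf1, vegfaa, fosab, npas4a, egr1, pcna, ppargc1a, mki67, gfap, mbpa, apoeb, cdkn1a, dcx); fosab and dcx matched no identifier.

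Gene lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes. The test was repeated with the correlation estimated from the data, and with fry, which tests whether a list's genes move on balance in a single direction. Of 73 list results past the threshold with the preset correlation, 0 passed with an estimated correlation and 13 passed with fry. Called members are counted after adjustment over all genes and, in addition, adjusted over the list alone. A list score is the mean log2 CPM of the list's genes in a library; scores of the 9 other-cell lists were compared between groups in 36 two-sided exact permutation tests, in which 5 against 5 libraries cannot give a p below 0.00794.

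Exercise effects at both ages, and age effects with and without exercise, were set against each other by Pearson's r and Spearman's rho across genes, which are not independent replicates. For exercise at 3 years against age without exercise, which share the unexercised 3-year libraries, 50 simulations of unchanged groups and 20 fits with those libraries split between the effects were added.

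The following other settings were set before the data were examined: DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1), no filter beyond 1 count in any library, a mean of at least 5 CPM, a fit of only the groups compared, 1 surrogate variable (sva 3.50.0), an erythrocyte covariate, and leaving out each library in turn. Settings added after seeing the data were 4 tissue scores as covariates, leaving out libraries whose muscle, retina or epidermis score lay over 2 log2 units above the median, and removing trends on gene length. Also added were thinning every library to the smallest total, the recomputed RPKM, leaving out both unexercised libraries numbered 1, and leaving out each library for the correlations of effects. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

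The edgeR step was tested on simulated data with 200 of 21148 genes changed 1.5-fold to 4-fold and a list of 30 others raised 1.3-fold. For exercise at 3 years, 40.3% of the genes changed 1.5-fold, 59.7% of those changed 2-fold and 89.4% of those changed 4-fold were called, with 4 of 20918 unchanged genes called. For age with exercise these shares were 32.8%, 61.2% and 93.9%, with 2 unchanged genes called. Simulated genes varied independently of each other, without libraries that stand apart, so these shares need not hold for the real libraries. Library totals lay between 23.4 and 34.6 M counts, so counting error is small for all but low genes, and the spread between libraries sets the precision: the median standard error of a log2 fold change was 0.18 for both age comparisons. No library was left out of the main tests. Results of 2 called genes are not reported here, though both stay in the counts and list tests, and 1 of them was left out of the search for outlying values. Within groups, the 40 pairs of libraries differed by far more than sampling noise, with a chi-square of at least 18.8 per gene.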

Results

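The brain transcriptome of male zebrafish was measured by RNA sequencing at 1 year and at 3 years of age, in fish that had swum in a swim tunnel and in fish that had not, with 5 libraries in each of the 4 groups. The layout asks how the brain's gene expression differs after physical exercise, how it differs between ages, and whether the exercise difference depends on age. Ages were compared between different fish, so an age difference cannot be told apart from other differences between them, such as in rearing or genotype. Words such as rose and fell describe differences between groups of fish. Libraries held between 23.4 and 34.6 M counts. The mean per group was 29.5 ± 2.32 M (SD, n = 5) in 1-year unexercised fish, 29.4 ± 3.39 M in 1-year exercised fish, 27.9 ± 2.17 M in 3-year unexercised fish and 31.6 ± 3.25 M in 3-year exercised fish.

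The main axis of variation separated most libraries by age. On the first principal component of log2 CPM, which carried 21.8% of the variance, all 5 exercised 1-year libraries and 4 of the 5 unexercised ones had positive scores, and 9 of the 10 3-year libraries had negative ones. The exceptions were 1-year unexercised replicate 1, at -41.5, and 3-year unexercised replicate 1, at 24.9. The farthest library was 3-year exercised replicate 1, at -87.9. The second component carried 13.1% of the variance, and the scores of all 4 groups overlapped on it.

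**Figure D1:**
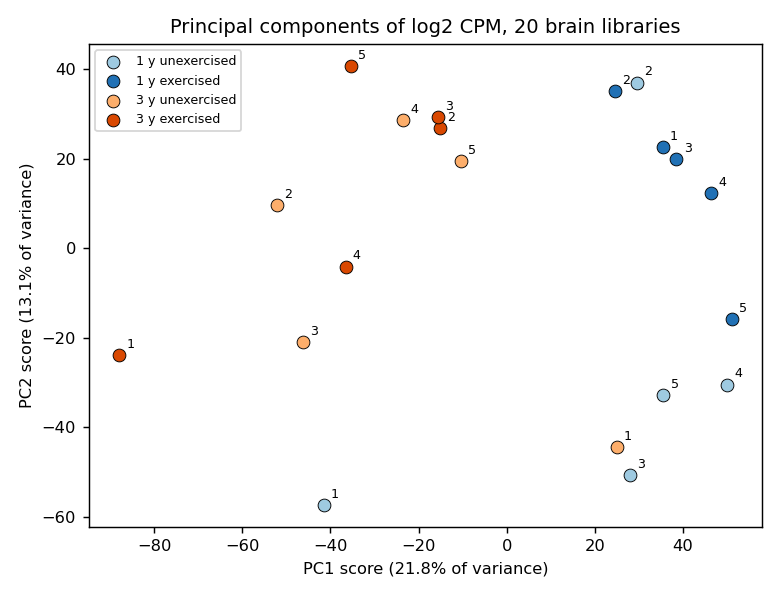
Scores of the 20 libraries on the principal components PC1 (21.8% of variance) and PC2 (13.1% of variance) of log2 CPM; each point is a library, coloured by group and numbered by replicate. Most 1-year libraries lie at positive PC1 scores and most 3-year libraries at negative ones, while replicate 1 of each unexercised group lies on the other side.

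Some libraries had high scores in lists of tissues that dissection can carry over, though carry-over itself was not tested. Libraries described below as having carried-over tissue are those past the limit set on the muscle, retina or epidermis score. The score of the retina and pineal list, which holds opsins and other phototransduction genes, was 3.65 in 1-year exercised replicate 3, 3.20 in 3-year exercised replicate 2 and 3.43 in 3-year exercised replicate 4, on a scale of mean log2 CPM. In all other libraries it lay between -0.25 and 0.63, so the libraries with a high score were all of exercised fish. The muscle score was highest in 1-year unexercised replicate 1 (4.59) and 3-year exercised replicate 1 (4.62), and the epidermis score in 1-year unexercised replicate 1 (5.51) and 3-year unexercised replicate 3 (4.65). The pituitary score was highest in 3-year exercised replicate 1 (2.80, with 1.12 or less in the others). None of 36 exact permutation tests of the 9 other-cell scores passed after Benjamini-Hochberg adjustment. The smallest exact p, 0.00794, was that of the lymphocyte and the neutrophil scores for age with exercise, which were higher by 1.15 and 0.60 at 3 years (adjusted p = 0.143 for each). It is the smallest exact p that 5 against 5 can give. Over 36 tests, neither 1 score nor 2 at that p can pass after adjustment, so the failure does not show that scores are alike.

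**Figure D2:**
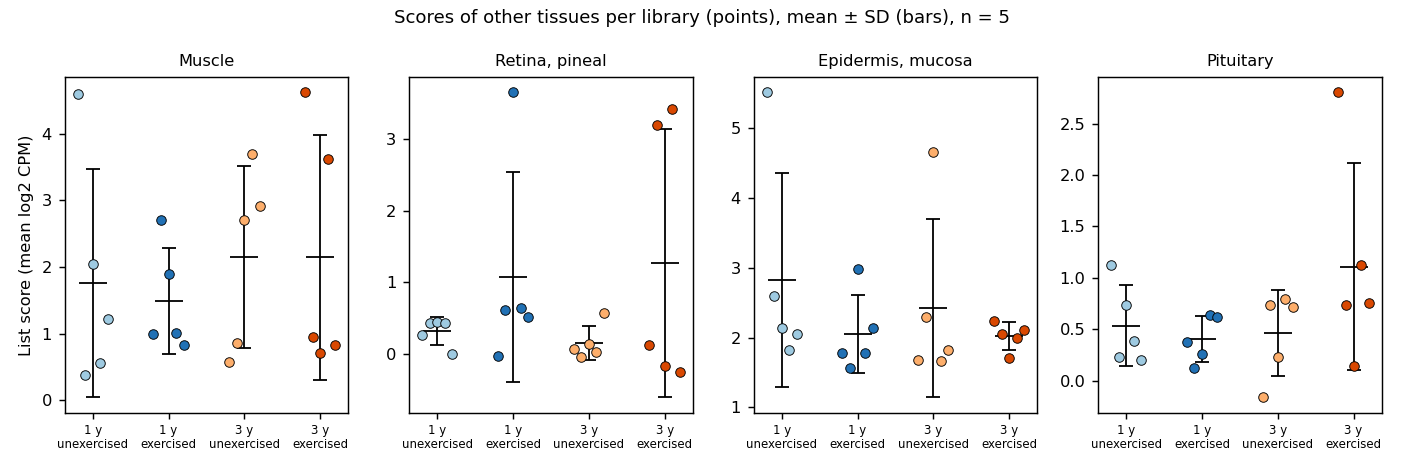
Scores (mean log2 CPM of the list's genes) of the muscle, retina and pineal, epidermis and pituitary lists in each library, by group; points are libraries, and bars give the mean ± SD (n = 5). A few libraries stand far above the rest, and the 3 with a high retina and pineal score (3.65, 3.20 and 3.43) are all of exercised fish.

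At 1 year, 4 genes differed between exercised and unexercised fish, 1 higher and 3 lower of 21148 tested. FOXO1 (ENSDARG00000099555), a transcription factor of the insulin and fasting response, was higher after exercise (log2 fold change 0.81 ± 0.13, adjusted p = 0.0421). ZNF395 (ENSDARG00000024195), a zinc finger protein, fell from 44.4 ± 6.15 to 23.6 ± 2.45 CPM (log2 fold change -0.92 ± 0.12, adjusted p = 0.00933). HSF2, a heat shock transcription factor (log2 fold change -0.79 ± 0.13, adjusted p = 0.0421), and DDB2, a DNA damage recognition protein (log2 fold change -0.67 ± 0.11, adjusted p = 0.0421), were also lower. Of the genes with the next smallest p, gstt2 (0.90 ± 0.16), INHBA (ENSDARG00000024759) (1.3 ± 0.23), CLOCK (ENSDARG00000003631) (0.59 ± 0.11) and YME1L1 (ENSDARG00000075192) (0.67 ± 0.13) had positive log2 fold changes. CRY2 (-0.38 ± 0.07) and tefa (-0.48 ± 0.09) had negative ones. Adjusted p of these 6 genes were 0.0673 to 0.077.

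Genes set in advance for their link to exercise did not pass at 1 year. PPARGC1A, a regulator of mitochondrial biogenesis, had a log2 fold change of 0.75 ± 0.20 (adjusted p = 0.153), and BDNF, a neurotrophin, of 0.14 ± 0.19 (adjusted p = 0.808). The activity-induced gene egr1 stood at -1.35 ± 0.36 (adjusted p = 0.161) and the NPAS4 identifiers ENSDARG00000055752 and ENSDARG00000087753 at -1.93 ± 0.58 and -0.74 ± 0.27 (adjusted p = 0.226 and 0.322). Log2 fold changes of IGF1, PCNA and the VEGFA identifiers ENSDARG00000034700 and ENSDARG00000103542 were 0.09 ± 0.13, -0.13 ± 0.07, -0.01 ± 0.10 and -0.07 ± 0.12, with adjusted p of 0.527 to 0.984. Over all genes, 0 members of the immediate early list were called with edgeR, but 14 of 27 were lower when adjusted over the list alone, and the list's median log2 fold change was -0.64 (adjusted camera p = 8.91e-09, and adjusted p = 0.58 with an estimated correlation). Of the glucocorticoid target list 1 member, FOXO1 (ENSDARG00000099555), was called, and 9 higher and 4 lower of 29 adjusted over the list alone (adjusted camera p = 3.93e-05, and adjusted p = 0.39 with an estimated correlation). Clock genes had 0 called in edgeR, and 7 higher and 9 lower of 33 adjusted over the list alone (adjusted camera p = 0.94, and adjusted p = 0.986 with an estimated correlation). The median log2 fold change of the microglial list was -0.61, with 0 members called in edgeR over all genes or over the list alone (adjusted camera p = 5.29e-07, and adjusted p = 0.727 with an estimated correlation). The microglial score of unexercised replicate 1, which also had the highest muscle and epidermis scores of its group, was 4.28, that of the other unexercised libraries 2.88 to 3.6 and that of the exercised ones 2.78 to 3.09. Without this library the median of the microglial list was -0.36. The epidermis list had a median of -1.45 (adjusted camera p = 0.00119, and adjusted p = 0.919 with an estimated correlation), and of -0.05 without that library. The interferon and antigen presentation list had a median of -0.61 with 0 called in edgeR over all genes or over the list (adjusted camera p = 0.00193, and adjusted p = 0.919 with an estimated correlation), and of -0.26 without the same library. In the synaptic list 36 of 38 genes had positive log2 fold changes, with a median of 0.16 and 0 called in edgeR over all genes or over the list (adjusted camera p = 3.93e-05, and adjusted p = 0.727 with an estimated correlation). Adjusted over the list alone, 10 of 24 muscle genes were lower and 8 of 23 retina and pineal genes higher, beside the muscle score of 4.59 in unexercised replicate 1 and the retina score of 3.65 in exercised replicate 3. Leaving out 1-year unexercised replicate 5 raised the count of calls from 4 to 197, and it was 2, 2, 2, 1, 1, 0 and 0 without unexercised replicates 1, 2 and 3 and exercised replicates 2, 4, 3 and 5. DESeq2 called 268 genes.

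At 3 years, 6 genes differed with exercise, 3 in each direction. PER2, a repressor of the circadian clock that light induces in fish, rose from 83.6 ± 4.01 to 163 ± 19.4 CPM (log2 fold change 0.96 ± 0.14, adjusted p = 0.0107). PELI3, a ubiquitin ligase of innate immune signalling (log2 fold change 0.70 ± 0.10, adjusted p = 0.0107), and BAIAP2 (ENSDARG00000103333), which links membranes to actin (log2 fold change 1.21 ± 0.20, adjusted p = 0.0481), were higher. cyp27a1.1, a sterol 27-hydroxylase, fell from 21.1 ± 0.835 to 12 ± 1.2 CPM (log2 fold change -0.82 ± 0.08, adjusted p = 5.81e-05). A further family member, CYP27A1 (ENSDARG00000069186) (log2 fold change -1.67 ± 0.28, adjusted p = 0.0481), and SUZ12 (ENSDARG00000098924), of the Polycomb repressive complex (log2 fold change -0.55 ± 0.09, adjusted p = 0.0481), were also lower. Of the genes with the next smallest p, syt13, INHBA (ENSDARG00000024759) and ULK2 had log2 fold changes of 0.46 ± 0.09, 1.19 ± 0.23 and 0.74 ± 0.14, with adjusted p of 0.114 to 0.146, above the threshold.

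Exercise genes set in advance did not pass at 3 years either, with adjusted p of 0.448 to 0.937. PPARGC1A had a log2 fold change of 0.50 ± 0.20, BDNF of 0.35 ± 0.19 and egr1 of -0.79 ± 0.36. The immediate early list had 0 members called in edgeR over all genes or over the list alone and a median log2 fold change of -0.22 (adjusted camera p = 0.481, and adjusted p = 0.979 with an estimated correlation), or -0.10 without unexercised replicate 3. The interferon list had a median of 0.22 (adjusted camera p = 0.0197, and adjusted p = 0.979 with an estimated correlation), which lay between -0.04 (without exercised replicate 1) and 0.71 (without unexercised replicate 2) with a library left out. The clock list had 1 called member, PER2, and 3 higher and 1 lower of 33 adjusted over the list alone (adjusted camera p = 0.000248, and adjusted p = 0.954 with an estimated correlation). Of the retina and pineal list, 12 of 23 were higher adjusted over the list alone with 0 called over all genes by edgeR (adjusted camera p = 0.000248, and adjusted p = 0.954 with an estimated correlation), with the high scores in replicates 2 and 4 of the exercised fish. The cholesterol biosynthesis list had 4 of 27 lower adjusted over the list alone (adjusted camera p = 3.28e-05, and adjusted p = 0.954 with an estimated correlation). The count of calls was 3 without 3-year unexercised replicate 3, without exercised replicate 4 and without exercised replicate 5, and DESeq2 called 118.

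A single gene was called for an exercise effect that differed between ages, a count that 12 of 100 splits of the libraries reached, so chance cannot be excluded. cyp27a1.1 was at 18.5 ± 1.7 and 17.4 ± 0.955 CPM without and with exercise at 1 year, and at 21.1 ± 0.835 and 12 ± 1.2 CPM at 3 years. The effects differed by -0.73 ± 0.11 on the log2 scale (adjusted p = 0.0485). The adjusted p lay just under the threshold, and of the 20 fits with a library left out only those without 1-year unexercised replicate 3, 1-year unexercised replicate 5 or 3-year exercised replicate 5 called this gene. The fit without 3-year unexercised replicate 2 called 1 other gene, and DESeq2 called 12 genes, this one among them. For DDB2 and PER2 the differences were 0.75 ± 0.15 and 0.91 ± 0.19 (adjusted p = 0.696 and 0.696). In 1004 genes the unadjusted p was below 0.05, 4.75% of those tested. The microglial and interferon lists had median differences of 0.65 (adjusted camera p = 7.81e-08, and adjusted p = 0.483 with an estimated correlation) and of 0.86 (adjusted camera p = 9.36e-07, and adjusted p = 0.483 with an estimated correlation), with 0 members called in edgeR over all genes or over the list alone. The microglial difference was 0.41 without 1-year unexercised replicate 1, 0.40 without 3-year exercised replicate 1 and 1.00 without 3-year unexercised replicate 2. The interferon difference was 0.39 and 0.46 without the first 2 of these. The immediate early list had a median difference of 0.51, also with 0 called in edgeR in either adjustment (adjusted camera p = 2.91e-06, and adjusted p = 0.483 with an estimated correlation). Of the clock list, 8 of 33 members had a larger effect at 3 years adjusted over the list alone (adjusted camera p = 0.00176, and adjusted p = 0.483 with an estimated correlation). Across genes the exercise effects at 1 and 3 years were weakly related, with Pearson's r of 0.164, Spearman's rho of 0.215 and the same sign in 59.4% of genes. With a library left out rho lay between 0.101 (without 3-year unexercised replicate 3) and 0.403 (without 3-year exercised replicate 1).

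Averaged over both ages, 192 genes differed with exercise, 144 of them higher and 48 lower. Among the largest increases was hsd20b2, a steroid dehydrogenase that inactivates cortisone (log2 fold change 1.67 ± 0.28, adjusted p = 0.00973). INHBA (ENSDARG00000024759), a subunit of activin, was higher as well (log2 fold change 1.25 ± 0.16, adjusted p = 0.00326). It stood at 5.22 ± 1.74 and 12.9 ± 3.64 CPM at 1 year and at 4.56 ± 0.816 and 10.4 ± 2.38 CPM at 3 years, without and with exercise. ARHGAP19 (1.75 ± 0.32), abhd5a, a lipase co-activator (1.5 ± 0.34), FAM107B (1.13 ± 0.23), ssh2b (1.06 ± 0.17) and PRR5 (1.05 ± 0.19) were also among the top increases, given as log2 fold changes, with adjusted p of 0.00787 to 0.0444. Among the named genes the largest decrease was in egr4, an activity-induced transcription factor, which fell from 244 ± 109 to 54.9 ± 22 CPM at 1 year and from 139 ± 121 to 44.6 ± 18.5 CPM at 3 years (log2 fold change -1.90 ± 0.37, adjusted p = 0.0203). At 3 years unexercised replicates 1 and 2 stood at 37.7 and 40 CPM, within the range of the exercised libraries (24 to 70.6 CPM). Lower genes outside the immediate early list included CYP27A1 (ENSDARG00000069186) (-1.04 ± 0.20), SH3TC2 (-0.72 ± 0.16) and ZNF395 (ENSDARG00000024195) (-0.62 ± 0.09), with adjusted p of 0.0039 to 0.0355.

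Several lists held members of this averaged change. Of 27 immediate early genes, which neuronal activity induces, 3 fell (egr4, ier2a at -1.20 ± 0.23 and ier2b at -0.98 ± 0.21) and 12 adjusted over the list alone (adjusted camera p = 0.000138, and adjusted p = 0.973 with an estimated correlation). The score of this list was 4.99 ± 0.37 without and 4.31 ± 0.18 with exercise at 1 year, and 4.37 ± 0.68 and 4.30 ± 0.13 at 3 years. In 3-year unexercised replicates 1 and 2 it was 3.53 and 3.76, below the lowest score of the exercised 3-year libraries (4.09). Of 29 glucocorticoid targets 4 rose, FOXO1 (ENSDARG00000099555), hsd20b2, zbtb16b (0.61 ± 0.12) and GLUL (ENSDARG00000100003) (0.54 ± 0.12), and 9 rose and 3 fell adjusted over the list alone (adjusted camera p = 0.000229, and adjusted p = 0.932 with an estimated correlation). Of 33 clock genes 5 rose and 3 fell, and 12 and 9 adjusted over the list alone. Among them were CLOCK (ENSDARG00000003631) (0.48 ± 0.08), nr1d4a (0.60 ± 0.11) and PER2 (0.51 ± 0.10) upward and NR1D2 (-0.58 ± 0.09) downward. The clock list as a whole did not pass (adjusted camera p = 0.0669, and adjusted p = 0.973 with an estimated correlation). Of 35 hypoxia genes 3 rose, and 4 adjusted over the list alone (adjusted camera p = 0.0399, and adjusted p = 0.973 with an estimated correlation). They were hif1al (1.07 ± 0.23), a relative of the hypoxia-inducible factor alpha subunit, PFKFB4 (1.13 ± 0.25), which sets the level of an activator of glycolysis, and PDK2 (ENSDARG00000020876) (0.77 ± 0.18), which restrains pyruvate oxidation. Counts of calls moved both ways with a library left out. Immediate early calls were 1 without 1-year exercised replicate 3, and 5, 7 and 6 without 1-year unexercised replicate 5 and 3-year unexercised replicates 1 and 2. Glucocorticoid target calls were 9 without 1-year unexercised replicate 5. Clock calls were 13 without it, and 5 without 1-year unexercised replicate 4 and without 1-year exercised replicate 3. Hypoxia calls were 0 or 1 without 1-year unexercised replicates 1, 3 or 4, 1-year exercised replicates 2, 3 or 5, 3-year unexercised replicates 1, 3 or 4, or 3-year exercised replicates 2, 4 or 5. All genes named from these lists had adjusted p of 0.00787 to 0.0479.

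PPARGC1A (log2 fold change 0.62 ± 0.14, adjusted p = 0.0382) was the called member of 26 neurotrophic and growth factor genes, and BDNF, at 0.25 ± 0.13, was not called (adjusted p = 0.42). The radial glia list had 2 of 26 members higher, her15.1 (0.66 ± 0.13) and GLUL (ENSDARG00000100003). This GLUL identifier is counted in the glucocorticoid target list too. The lists name separate copies, glula and glulb, so it can be the intended gene of only 1 of them. The heat shock list had HSP90AA1 higher (0.44 ± 0.08) and HSF2 lower (-0.57 ± 0.09), the lysosome list ULK2 (0.53 ± 0.10) and ctsla (0.36 ± 0.08) higher, and the endothelial list stab1 higher (0.70 ± 0.14). In the retina and pineal list 14 of 23 members were higher adjusted over the list alone and 0 over all genes in edgeR (adjusted camera p = 0.000362, and adjusted p = 0.973 with an estimated correlation), while all 3 libraries with a high retina score were exercised. In the epidermis list 8 of 26 were lower adjusted over the list alone (adjusted camera p = 0.0025, and adjusted p = 0.973 with an estimated correlation), while both libraries with a high epidermis score were unexercised. The list's median of -1.15 was -0.59 without 1-year unexercised replicate 1 and -0.64 without 3-year unexercised replicate 3.

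The size of the averaged exercise change depended on the libraries and settings. With upper-quartile scaling 134 genes were higher and 74 lower, and with gene-length trends removed 127 and 73. With 4 tissue scores as covariates 7 genes were called, and without the 7 libraries with carried-over tissue 1 gene. All 192 genes kept their direction in both, both alternatives being chosen after seeing the data. A kept direction was likely in advance, since these genes had been called in fits that held the same libraries. Counts were 90, 111 and 434 without 1-year unexercised replicates 3, 4 and 5, and 89 and 106 without 1-year exercised replicates 3 and 5. They were 116 and 112 without 3-year unexercised replicates 3 and 4, and 342, 101 and 97 without 3-year exercised replicates 1, 4 and 5. At PFKFB4 and hif1al, 1-year unexercised replicate 5 stood at 174 and 202 CPM, within or above the range of the exercised fish, and the other 4 unexercised libraries at 42.1 to 48.9 and 53.7 to 61.2 CPM.

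**Figure D3:**
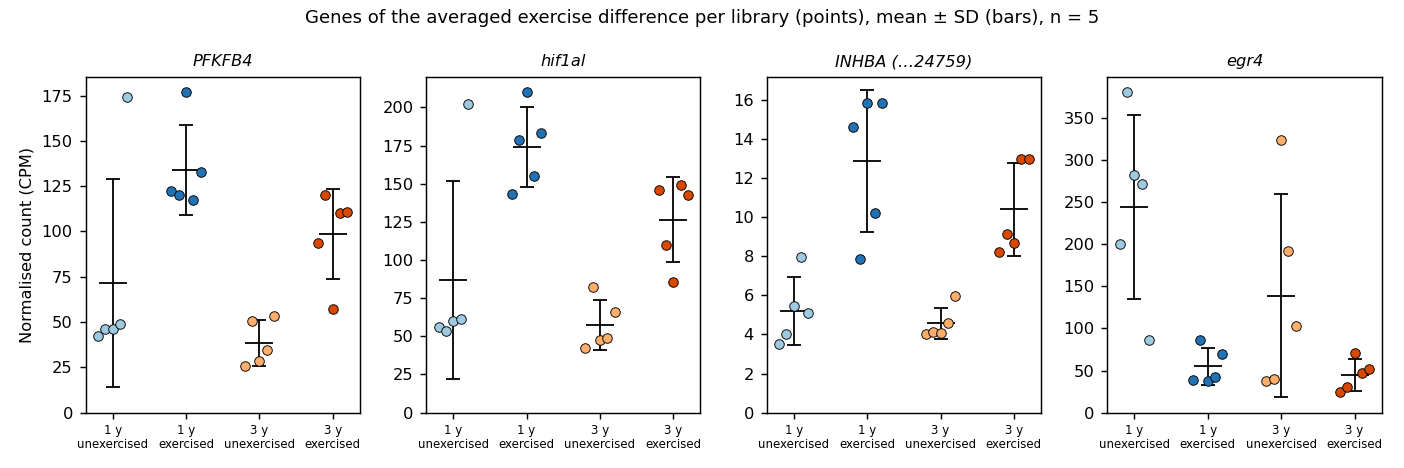
Normalised counts (CPM) of PFKFB4, hif1al, INHBA (ENSDARG00000024759) and egr4 in each library, by group; points are libraries, and bars give the mean ± SD (n = 5). PFKFB4, hif1al and INHBA lie higher in most exercised fish of both ages, and 1-year unexercised replicate 5 is at 174 CPM for PFKFB4. egr4 lies lower in most exercised fish at 1 year. At 3 years its levels overlap, with unexercised replicates 1 and 2 (37.7 and 40 CPM) within the exercised range (24 to 70.6 CPM).

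Between 1 and 3 years without exercise, 124 genes differed, 47 higher and 77 lower at 3 years, and genes of the circadian clock were among the largest changes in both directions. rorcb, a nuclear receptor that activates clock genes, rose from 16.3 ± 1.06 to 90.2 ± 25.9 CPM (log2 fold change 2.47 ± 0.16, adjusted p = 8.62e-08). NR1D2, a repressor in the same loop, fell from 389 ± 37.4 to 142 ± 18.5 CPM (log2 fold change -1.46 ± 0.13, adjusted p = 1.36e-05). PER1 (ENSDARG00000012499), a core repressor of the clock, fell from 141 ± 20.3 to 45.4 ± 9.38 CPM (log2 fold change -1.64 ± 0.13, adjusted p = 1.69e-06). PER1 (ENSDARG00000056885), PER3, NR1D1, ciarta, dbpa and, outside the list, cipca fell as well, with log2 fold changes of -1.78 ± 0.23, -1.58 ± 0.33, -2.06 ± 0.29, -2.24 ± 0.29, -1.33 ± 0.24 and -1.52 ± 0.19. rorca and nfil3-5 rose by 1.09 ± 0.11 and 1.78 ± 0.28. These 8 genes had adjusted p of 4.95e-05 to 0.026. Of 33 clock genes tested, 5 rose and 13 fell, and 8 and 18 adjusted over the list alone (adjusted camera p = 2.29e-07, and adjusted p = 0.158 with an estimated correlation). With an unexercised library left out, 16 to 19 clock genes were called, of which 16 to 18 were among these 18.

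**Figure D4:**
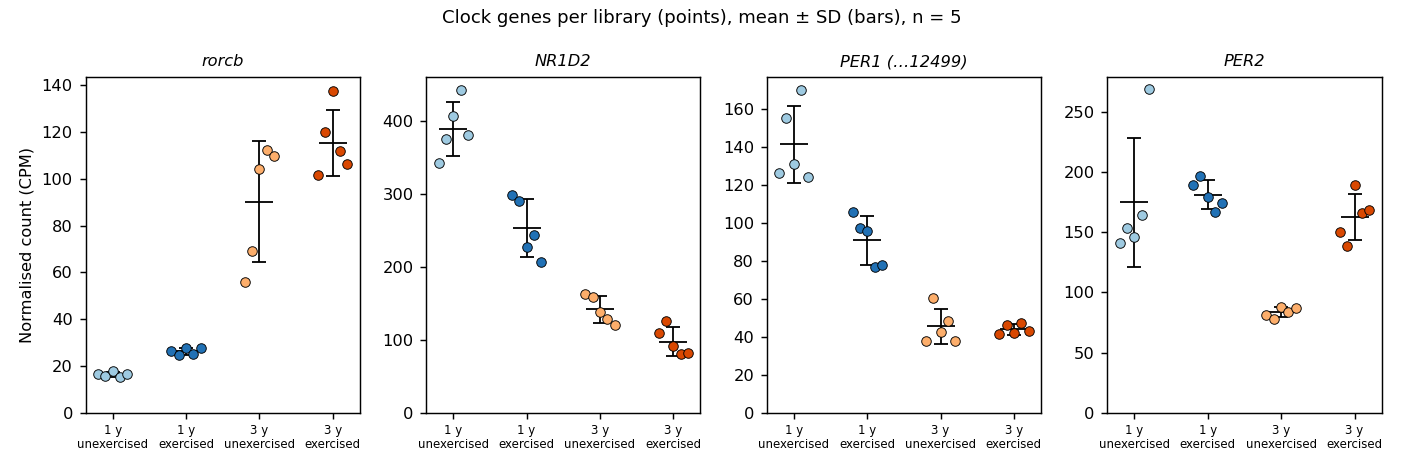
Normalised counts (CPM) of rorcb, NR1D2, PER1 (ENSDARG00000012499) and PER2 in each library, by group; points are libraries, and bars give the mean ± SD (n = 5). Mean rorcb rises and mean NR1D2 falls from group to group, from 1-year unexercised (16.3 and 389 CPM) to 3-year exercised fish (115 and 97.4 CPM).

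Outside the clock, the larger increases at 3 years included fbxl3l (2.29 ± 0.33), pcyt1bb (2.13 ± 0.45), tnfrsf1b, a receptor for tumour necrosis factor (1.95 ± 0.39), stm (1.81 ± 0.38), TGM1 (ENSDARG00000101407) (1.57 ± 0.33) and CRYAB (ENSDARG00000101380), a small heat shock protein (1.5 ± 0.27), with adjusted p of 0.0011 to 0.0338. Decreases included cngk (-3.02 ± 0.66, adjusted p = 0.044) and wdr76 (-1.41 ± 0.24, adjusted p = 0.00602). Of 32 heat shock and chaperone genes, CRYAB (ENSDARG00000101380) rose and 3 fell, HSF2 (-0.74 ± 0.13), HSPA4 (ENSDARG00000004754) (-0.47 ± 0.09) and HSPA4L (-0.47 ± 0.10). In the same list 1 rose and 12 fell adjusted over the list alone (adjusted camera p = 1.81e-08, and adjusted p = 0.158 with an estimated correlation). Of 27 cholesterol biosynthesis genes 2 fell, among them FDFT1 (-0.72 ± 0.15), and 3 fell adjusted over the list alone (adjusted camera p = 1.81e-08, and adjusted p = 0.378 with an estimated correlation). The heat shock genes that fell and FDFT1 had adjusted p of 0.00562 to 0.0256. Both called members of the glucocorticoid target list were the PER1 genes. Microglial genes had a median log2 fold change of 0.64, with 0 of 28 called over all genes in edgeR and 7 higher adjusted over the list alone (adjusted camera p = 6.45e-09, and adjusted p = 0.571 with an estimated correlation). Interferon and antigen presentation genes had a median of 0.76, with 2 of 30 higher adjusted over the list alone (adjusted camera p = 8.81e-06, and adjusted p = 0.65 with an estimated correlation). In 3-year unexercised replicate 2 the microglial and interferon scores were 4.86 and 4.90, and in the other libraries of its group 3.59 to 4.26 and 3.19 to 4.18. Without it the medians of the lists were 0.35 and 0.25, and without 1-year unexercised replicate 1 they were 1.00 and 1.04. Oxidative phosphorylation genes had a median of -0.13, with none past the threshold in either adjustment in edgeR (adjusted camera p = 6.45e-09, and adjusted p = 0.65 with an estimated correlation). Genes of ageing set in advance did not pass, with log2 fold changes of 0.45 ± 0.21 for GFAP, 0.49 ± 0.25 for cdkn1a, 0.10 ± 0.30 for mki67, 0.07 ± 0.29 for apoeb, -0.22 ± 0.23 for mbpa and -0.17 ± 0.07 for PCNA (adjusted p = 0.299 to 0.939).

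The number of calls was 78 without 1-year unexercised replicate 4, 81 without 3-year unexercised replicate 4 and 257 without 3-year unexercised replicate 1. It was 533 with DESeq2, 271 with 1 surrogate variable and 43 in a fit of the compared groups alone. Of the settings chosen after seeing the data, leaving out both unexercised libraries numbered 1 gave 559 and leaving out the 7 libraries with carried-over tissue gave 19. Without those 7 libraries all 124 genes kept their sign, which was likely in advance, as the remaining libraries had helped to call them. The median log2 fold change of these genes in the direction called was 0.66 after 0.73, and their median standard error 0.15 after 0.12. Recomputed RPKM gave 77 higher and 73 lower, and the deposited RPKM with a pseudocount of 0.1 gave 12 and 31.

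Between 1 and 3 years with exercise, 2252 genes differed, 1432 higher and 820 lower at 3 years, and the lists with the largest shares of increased members were those of immune cells and antigen presentation. Of 28 microglia and macrophage genes 20 rose and 0 fell, and 24 rose adjusted over the list alone, with a median log2 fold change of 1.41 (adjusted camera p = 2.06e-16, and adjusted p = 0.338 with an estimated correlation). Among them were the galectin gene lgals9l1, from 12.3 ± 2.27 to 81.3 ± 51.1 CPM (log2 fold change 2.72 ± 0.46, adjusted p = 0.00374), and IRF8, a transcription factor that microglia need, from 6.37 ± 1.28 to 26.4 ± 14.7 CPM (log2 fold change 2.05 ± 0.38, adjusted p = 0.00555). The cathepsin gene ctss2.2 (2.00 ± 0.37) and havcr1 (1.23 ± 0.21) rose too. Of 30 interferon and antigen presentation genes 19 rose and 0 fell, and 22 rose adjusted over the list alone (adjusted camera p = 1.3e-12, and adjusted p = 0.338 with an estimated correlation). Their log2 fold changes included 2.58 ± 0.50 for mhc1zaa, 1.76 ± 0.34 for cd74b, 1.67 ± 0.34 for cd74a and 1.77 ± 0.39 for b2m. The named genes of both lists had adjusted p of 0.00374 to 0.0111. Without 3-year exercised replicate 1, whose muscle and pituitary scores were also the highest of its group, 14 microglial and 8 interferon genes were called.

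Part of the lysosome and lymphocyte lists was higher too. Of 33 lysosome and autophagy genes 12 rose, and 15 adjusted over the list alone, or 7 over all genes without 3-year exercised replicate 1 (adjusted camera p = 9.96e-06, and adjusted p = 0.267 with an estimated correlation). Log2 fold changes were, for example, grna at 1.87 ± 0.33, CTSZ at 0.89 ± 0.19, SQSTM1 at 0.50 ± 0.11 and CD63 at 0.54 ± 0.12. Of 22 lymphocyte genes 6 rose, and 14 adjusted over the list alone (adjusted camera p = 3.3e-05, and adjusted p = 0.409 with an estimated correlation). Among them were IKZF1 (1.66 ± 0.37) and il7r (2.59 ± 0.71). Without 1-year exercised replicates 1, 3, 4 or 5 or 3-year exercised replicate 1, only 1 or 2 lymphocyte genes were called. Of 15 neutrophil genes 3 rose, MMP9, adam8a and cxcl18b, and 4 adjusted over the list alone (adjusted camera p = 0.0115, and adjusted p = 0.451 with an estimated correlation). Without any one of the 1-year exercised libraries or without 3-year exercised replicate 1, 0 or 1 neutrophil gene was called in edgeR. In the p53 and senescence list 4 of 31 rose, and 4 adjusted over the list alone, including cdkn1a (0.94 ± 0.25), a cell-cycle inhibitor, and fas (1.84 ± 0.51). The p53 list as a whole did not pass (adjusted camera p = 0.144, and adjusted p = 0.73 with an estimated correlation). In edgeR 0 of its genes were called without 3-year exercised replicate 1, and 1 or 2 without 1-year exercised replicates 1 to 4. All genes named in these lists had adjusted p of 0.00407 to 0.0419.

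Most called genes of the sterol synthesis, energy metabolism and synaptic lists were lower. Of 27 cholesterol biosynthesis genes 17 fell and 0 rose, and 19 fell adjusted over the list alone, with a median log2 fold change of -0.56 (adjusted camera p = 8.31e-14, and adjusted p = 0.263 with an estimated correlation). SQLE (ENSDARG00000079946) fell by a log2 fold change of -1.65 ± 0.29, LSS of -1.23 ± 0.21 and MSMO1 of -1.02 ± 0.17. Of 91 oxidative phosphorylation genes 20 fell and 1 rose, and 38 fell and 1 rose adjusted over the list alone (adjusted camera p = 2.35e-12, and adjusted p = 0.451 with an estimated correlation). The changes were small, such as -0.40 ± 0.09 for SDHB and -0.35 ± 0.07 for UQCRFS1. Of 28 glycolysis genes 8 fell, and 10 adjusted over the list alone (adjusted camera p = 0.00495, and adjusted p = 0.451 with an estimated correlation). Examples were pgam1a (-0.54 ± 0.12) and PKM (ENSDARG00000099730) (-0.43 ± 0.09). The mean over the list, 0.18, had the opposite sign to its median of -0.16. Of 38 synaptic and neuronal genes 8 fell, and 14 adjusted over the list alone (adjusted camera p = 6.59e-09, and adjusted p = 0.338 with an estimated correlation). Among them were the neurofilament nefla (-0.98 ± 0.26), GAD2, which makes GABA (-0.53 ± 0.13), and SLC17A6 (ENSDARG00000041150), a vesicular glutamate transporter (-0.47 ± 0.10). The named genes had adjusted p of 0.00355 to 0.0221. Calls in the cholesterol list were 10 without 1-year exercised replicate 4 and 11 without 3-year exercised replicate 1. Those in the oxidative phosphorylation list were 32 without 1-year exercised replicate 2 and 7 to 13 without 1-year exercised replicates 3, 4 or 5 or 3-year exercised replicates 1, 2 or 3. In the glycolysis list they were 3 to 5 without 1-year exercised replicates 3, 4 or 5 or 3-year exercised replicates 1 or 3. In the synaptic list they were 3 to 5 without 1-year exercised replicates 1, 3, 4 or 5 or 3-year exercised replicates 1, 2 or 3.

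Clock genes differed with age in exercised fish as well, with 4 of 33 higher and 10 lower, and 5 and 12 adjusted over the list alone (adjusted camera p = 0.0185, and adjusted p = 0.451 with an estimated correlation). rorcb rose from 26.2 ± 1.45 to 115 ± 14.1 CPM and NR1D2 fell from 253 ± 40 to 97.4 ± 19.7 CPM (adjusted p = 7.67e-07 and 4.86e-05). Of 32 heat shock genes 7 fell, and 9 adjusted over the list alone (adjusted camera p = 0.000487, and adjusted p = 0.338 with an estimated correlation), such as the mitochondrial chaperonins HSPE1 (-0.37 ± 0.07) and HSPD1 (-0.38 ± 0.08). In the oligodendrocyte list 5 of 24 rose and 1 fell, and 7 and 1 adjusted over the list alone (adjusted camera p = 0.00905, and adjusted p = 0.66 with an estimated correlation). OLIG2 (0.76 ± 0.19) and SOX10 (0.58 ± 0.17), which specify the lineage, were higher, and GPR17, a marker of immature oligodendrocytes, was lower (-0.91 ± 0.21). There were 2 or 3 oligodendrocyte calls without 1-year exercised replicates 1, 3, 4 or 5 or 3-year exercised replicates 1 or 3. HDC, which makes histamine, fell (log2 fold change -0.91 ± 0.15, adjusted p = 0.00336), and IGF1 fell (log2 fold change -0.48 ± 0.13, adjusted p = 0.0253). The named heat shock and oligodendrocyte genes had adjusted p of 0.00573 to 0.0327. GFAP, apoeb, mki67, mbpa and PCNA were not called, with log2 fold changes of -0.07 ± 0.21, 0.29 ± 0.29, 0.74 ± 0.30, 0.07 ± 0.23 and 0.03 ± 0.07 (adjusted p = 0.119 to 0.89).

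**Figure D5:**
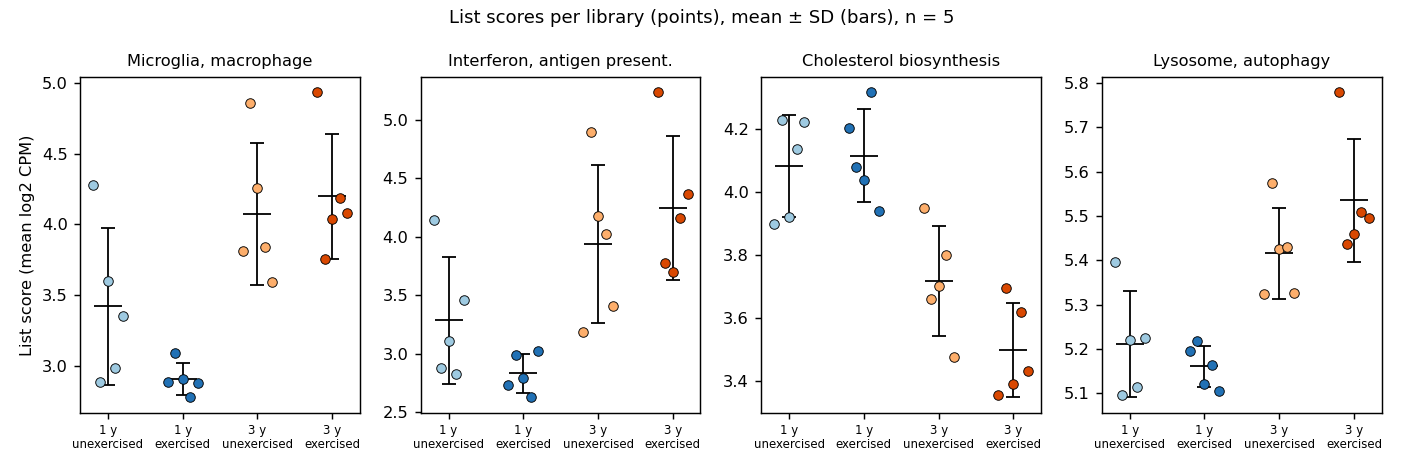
Scores (mean log2 CPM of the list's genes) of the microglia and macrophage, interferon and antigen presentation, cholesterol biosynthesis and lysosome and autophagy lists in each library, by group; points are libraries, and bars give the mean ± SD (n = 5). Exercised 3-year fish lie above exercised 1-year fish in the microglial, interferon and lysosome lists and below them in the cholesterol list.

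Some of the largest fold changes with age in exercised fish were of genes near 0 in one group or with a wide spread between libraries. On average, ifi44a6, tas2r200.1, cxcl11.4, gstk2 and ftr43 were at about 0.10 CPM or below in 1-year exercised fish. dicp1.16 averaged 0.01 CPM in 3-year exercised fish, so no fold is given for any of these genes. mhc2dab, a class II histocompatibility gene, rose from 3.24 ± 0.58 to 106 ± 131 CPM, with 3-year exercised libraries between 4.2 and 322 CPM, and lgals3bp.3 from 0.16 ± 0.09 to 5.76 ± 1.95 CPM (adjusted p = 0.0135 and 0.0107). In unexercised fish lgals3bp.3 spread widely at both ages, from 0.101 to 5.74 CPM at 1 year and from 0.0956 to 8.89 CPM at 3 years. FAH, an enzyme of tyrosine breakdown, fell from 6.48 ± 0.567 to 0.648 ± 0.179 CPM (log2 fold change -3.31 ± 0.57, adjusted p = 0.00374), while 3-year unexercised replicate 1 stood at 7.33 CPM. otoa, a gene of the inner ear, fell from 119 ± 78.2 to 5.62 ± 1.74 CPM (adjusted p = 0.0248), with exercised 1-year replicate 5 at 4.12 CPM and the other 4 between 115 and 225 CPM. In 3-year unexercised fish it was at 112 to 274 CPM in 3 libraries and at 3.59 and 3.84 CPM in 2, so its level also split within groups. The pituitary genes POMC, smtlb and prl and the muscle genes myhz1.1, myhz1.2 and myhz2 were called higher. None of the pituitary genes was called without 1-year exercised replicate 3 or without 3-year exercised replicate 1, and none of the muscle genes without 3-year exercised replicate 4. In edgeR fits without several other exercised libraries 1 of each was called. POMC stood at 169.7 CPM in 3-year exercised replicate 1 and at 0.673 to 2.65 CPM in the other 4 libraries of that group.

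The remaining lists had few called members for age with exercise, given here as counts over all genes and then adjusted over the list alone. Higher and lower members numbered 0 and 2, then 0 and 2, in the neurotrophic list, 1 and 0, then 1 and 0, in the radial glia list, 1 and 0, then none, in the proliferation list, and 1 and 1, then 1 and 1, in the monoamine and cholinergic list. They numbered 2 and 1, then 3 and 5, in the endoplasmic reticulum stress list, 1 and 3, then 1 and 5, in the glucocorticoid target list, 1 and 3, then 2 and 3, in the hypoxia list, and 1 and 2, then 1 and 2, in the oxidative stress list. In the ribosomal protein list they numbered 1 and 1, then none, in the collagen list 0 and 3, then 0 and 1, in the endothelial list 1 and 1, then none, and in the erythrocyte list 2 and 1, then 2 and 1. The epidermis and the ependymal lists each had 1 higher member, then none, and the muscle and pituitary lists each 3 higher, then 3. Immediate early, neuroblast, neuropeptide, complement and retina genes had no call in edgeR, over all genes or over the list, and 5573 of all genes had an unadjusted p below 0.05. Of these lists, 4 passed camera with the preset correlation. They were the ribosomal protein (adjusted camera p = 5.28e-05, and adjusted p = 0.73 with an estimated correlation) and the glucocorticoid target lists (adjusted camera p = 0.00169, and adjusted p = 0.361 with an estimated correlation). The others were the hypoxia (adjusted camera p = 0.0436, and adjusted p = 0.451 with an estimated correlation) and complement lists (adjusted camera p = 0.033, and adjusted p = 0.73 with an estimated correlation). Those lists with 3 or more calls had between 0 and 2 without some library of the exercised groups.

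The count for age with exercise also depended on single libraries. It was 855 without 3-year exercised replicate 1 and 1193, 1267 and 1293 without 1-year exercised replicates 3, 4 and 5, and leaving out the 7 libraries with carried-over tissue, chosen after seeing the data, left 4 calls. The split moved with the unit, to 1391 higher and 90 lower on the deposited RPKM, which shifts the median of all genes by 0.17, and to 1663 and 374 on the recomputed RPKM.

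Age effects with and without exercise were alike in direction. Of the 2252 genes called with exercise, 2163 (96.0%) had the same sign without exercise, where their median absolute log2 fold change was 0.37 against 0.71 with exercise. Of the 124 genes called without exercise, 123 had the same sign with exercise, and their medians were 0.73 without and 0.54 with exercise. Each set was chosen by its calls in one comparison, which favours the larger fold there, so these medians do not show which age effect is larger. Between the lists of calls, 38 genes were higher in both and 54 lower in both, where independent lists would share 3.18 and 2.99, and 0 went opposite ways. Across genes Pearson's r was 0.442 and Spearman's rho 0.512, with rho between 0.434 and 0.579 when a library was left out. The difference between these age effects is the same contrast as the age difference of the exercise effect, for which a single gene was called.

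Exercise at 3 years was set against age without exercise, to ask whether genes that differ with age move back or further with exercise. The covariance of log2 fold changes across genes was -0.0127 (Pearson's r = -0.0763), where unchanged groups sharing the same 3-year unexercised libraries gave -0.0677 in simulations. The difference from the simulated value was 0.0550, and with the shared libraries split between the effects the covariance averaged 0.0583 over 20 fits (0.00155 to 0.127). Under the stricter filter the split fits ran from -0.00129 to 0.0734. Simulated genes varied independently of each other, without libraries that stand apart, so the simulated value need not hold for the real libraries. The question therefore stays open.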

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

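The tests of time of day, of a larger age difference, of the share of calls up and of the group nearer to a library, and the control with random covariates were chosen after the results were seen. The fits with tissue scores, libraries left out together, gene-length trends removed and thinned counts were added after seeing the data. The other tests in this part were set before their results were seen.

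In 100 groups of 5 libraries, the highest or lowest value was set against the others by its gap to the nearest one over the whole range. In 14 of them the ratio was above 0.71. Chance gives about 5 in independent groups of normally distributed values, while these are partly CPM of genes that move together in the same libraries, so 14 does not show an excess. Unexercised 1-year replicate 5 stood above the other 4 of its group at PFKFB4 (174 CPM, others 42.1 to 48.9), hif1al (202 CPM, others 53.7 to 61.2), hsd20b2 (20.1 CPM, others 4.24 to 8.29) and PER2 (269.7 CPM, others 141 to 165). Exercised 1-year replicate 3 stood above its group at PFKFB4 (177 CPM, others 117 to 133) and in the retina and pineal score (3.65, others -0.04 to 0.63). Unexercised 3-year replicate 2 stood above its group at lgals9l1 (164 CPM, others 35.5 to 43.8), IRF8 (51.2 CPM, others 16.2 to 21) and hsd20b2 (6.85 CPM, others 3.91 to 4.39), and unexercised 3-year replicate 1 at FAH (7.33 CPM, others 0.459 to 1.29). POMC was at 169.7 CPM in exercised 3-year replicate 1 (others 0.673 to 2.65). The epidermis score was 5.51 in unexercised 1-year replicate 1 (others 1.82 to 2.59) and 4.65 in unexercised 3-year replicate 3 (others 1.66 to 2.29). The total count of exercised 1-year replicate 2, 23.4 M, lay below the others of its group (30.4 to 31.9 M). The exercise effect on cyp27a1.1 differed between ages by -0.73 ± 0.11 on the log2 scale in edgeR's test of the difference (adjusted p = 0.0485), a single call that the splits of the libraries do not set apart from chance.

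The labels were taken as given, though 2 libraries lay nearer to the other group at most genes of a comparison with many calls. In the age comparisons the other libraries did so at a smaller share. It ran from 1 of 78 genes (unexercised 1-year replicate 4) to 69 of 180 (unexercised 1-year replicate 1), each called without that library. Of the 197 genes called for exercise at 1 year in the fit without unexercised 1-year replicate 5 (4 with it), this library lay nearer to the exercised mean at 151, such as PFKFB4 and hif1al, and nearer to its own group at 46. Among the called genes where it stood with its own group were ZNF395 (ENSDARG00000024195) at 38.8 CPM (exercised 19.8 to 25.8), HSF2 at 37.4 CPM (24.8 to 28) and DDB2 at 19.4 CPM (12.3 to 14.8), so neither its label nor an exchanged one accounts for all of these genes. Of the 257 genes called for age without exercise in the fit without unexercised 3-year replicate 1 (124 with it), this library lay nearer to the 1-year mean at 144, such as FAH, and nearer to its own group at 113. With the 3-year fish it had rorcb at 55.6 CPM (1-year 15 to 27.7), PER1 (ENSDARG00000012499) at 37.9 CPM (1-year at least 76.7) and stm at 220 CPM (1-year at most 90.6), and again neither age label accounts for all of the genes. Another origin of these libraries stays open.

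Clock genes differed between ages without exercise, with 18 of 33 called. Tissue carried over in dissection and a single unexercised library are argued against as the whole cause. With the 4 tissue scores as covariates 16 clock genes were called, and with any unexercised library left out at least 16 of the same 18. Of the 18 genes, 13 were called the same way and all 18 had the same sign with exercise, which another time of sampling for the older fish and a clock that differs with age could both give. The hour of sampling is not given in the sources used here, and the numbers in the sample titles run group after group in the order in which mean rorcb rose (16.3, 26.2, 90.2 and 115 CPM); if they follow the order of sampling, hour and group cannot be told apart. A difference of the clock with age stays open, as untested.

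Age with exercise gave 2252 calls and age without exercise 124. Library depth is argued against as the whole cause, since 2146 genes were called with exercise in libraries thinned to the smallest total. Leaving out replicate 1 of both unexercised groups raised the count without exercise to 559, which lies between the bounds set in advance, so spread from those libraries may account for part of the gap and stays open. On the exercised side, leaving out 3-year exercised replicate 1 lowered the count with exercise to 855. Fits of the compared groups alone gave 43 calls without and 2419 with exercise, so the gap also depends on which groups share the estimate of spread. For a larger age difference in exercised fish, which stays open too, the mean over genes of the squared log2 fold change less the squared standard error was 0.170 without and 0.382 with exercise, and the difference stayed positive with any library left out (0.0978, without 3-year exercised replicate 1, to 0.264). It was also positive, but of another size, with the recomputed RPKM (0.0462), the deposited RPKM and a pseudocount of 1 (0.066), the stricter filter (0.0998), the libraries with carried-over tissue left out (0.103) and both unexercised libraries numbered 1 left out (0.130). With the surrogate variable it was 0.315. Of the 2252 genes, 1 was called for the difference itself. Leaving out the 7 libraries with carried-over tissue left 4 of the 2252 genes called on 2 to 4 libraries per group, with 2247 of the same sign, the median log2 fold change at 0.62 after 0.71 and the median standard error at 0.22 after 0.18. The same sign says little here, as the remaining libraries were part of the fit that called the genes.

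Exercise averaged over both ages gave 144 calls up and 48 down, and gene length is argued against as the whole cause of these calls, since 172 of the 192 genes were still called with trends on gene length removed. The calls were then 127 up and 73 down, so the share up went from 75% to 63.5%, and gene length as part of the cause of that share stays open. With the 4 tissue scores as covariates 7 were still called, which met the bound set in advance for carried-over tissue. All 192 kept their sign, which says little, as they had been called in the same libraries. The median log2 fold change went from 0.54 to 0.47 and the median standard error from 0.10 to 0.11. Smaller folds and larger errors thus both went with the loss of calls. In the control, 16 of 40 sets of 4 random covariates left 7 genes or fewer (median 19, range 0 to 140). The median ratio of log2 fold changes over the 40 sets was 0.986, so calls were lost there with little change in the folds. In 4 of 40 sets the folds were lowered as much as with the tissue scores (a median ratio of 0.912), so the count does not decide. The retina and pineal score alone left 26 genes called (muscle 178, epidermis 126, erythrocyte 162), and sets of 4 random covariates are no control for a single score. Carried-over tissue of that list may contribute to the averaged change and stays open. The hour of sampling stays open too, as 8 clock genes were among the 192. Mean rorcb without and with exercise was 16.3 and 26.2 CPM at 1 year, and 90.2 and 115 CPM at 3 years. An effect of exercise itself stays open, untested apart from these.

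Each count was set against 100 splits of the same libraries into groups of the same sizes, the real split included. For exercise at 1 year, 3 splits gave at least the real 4 calls, and the highest other gave 1245. For exercise at 3 years, 4 splits gave at least 6, with 20 the highest other. For the averaged exercise effect, 2 splits gave at least 192, with 1082 the highest other. For age without exercise, 2 splits gave at least 124, with 666 the highest other, and for age with exercise only the real split reached 2252, with 13 the highest other. In these 5 comparisons fewer than 5 of 100 splits reached the real count, the bound set in advance, without adjustment over the 6 comparisons. The splits are a sample, with both pairs of groups redrawn together, and 3 or 4 of 100 cannot be told from 5. Chance is therefore not excluded for exercise at 1 year or at 3 years. It is argued against, within that bound, for the averaged exercise effect and for both age comparisons. For the age difference of the exercise effect, 12 splits gave at least the real 1 call, with 549 the highest other, so chance cannot be excluded. The splits with several times the real count, in all comparisons except age with exercise, point to a structure among the libraries that the groups do not describe.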

How the results depend on the processing

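Tissue scores, libraries left out together, gene length, thinning, recomputed RPKM and the fits of the correlations with a library left out were chosen after seeing the data; all other alternatives were planned. Counts below are for exercise at 1 year, exercise at 3 years, the age difference of the exercise effect, exercise averaged over both ages, age without exercise and age with exercise, where edgeR called 4, 6, 1, 192, 124 and 2252 genes; counts within 1.5 times of these are left out. DESeq2 called 268, 118, 12, 660, 533 and 3403, and limma-voom 17 for exercise at 1 year and 3 at 3 years. The deposited RPKM gave 1, 1, 0, 17, 43 and 1481 with a pseudocount of 0.1 and 1, 1, 0, 16, 42 and 1349 with 1, and the recomputed RPKM 1, 3 and 0 for the first 3 comparisons. The stricter filter gave 10 for exercise at 1 year and 290 for the averaged effect, and correlations (rho) of effects of 0.359 for exercise and 0.619 for age, after 0.215 and 0.512. Without a filter, with 1 surrogate variable and with the erythrocyte covariate the age difference had 0 calls. The surrogate variable gave 7 for exercise at 1 year and 271 for age without exercise, and the erythrocyte covariate 1 for exercise at 1 year. Fits of the compared groups alone gave 8 for exercise at 1 year and 43 for age without exercise. Tissue scores gave 0, 1, 0 and 7 for the first 4 comparisons, leaving out the libraries with carried-over tissue 0, 0, 0, 1, 19 and 4, thinning 1 for exercise at 1 year, and leaving out both unexercised libraries numbered 1 gave 2, 0 and 559 for exercise at 1 year, the age difference and age without exercise. With fewer libraries the tests have less power; the cause of the other shifts was not tested.

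Without the libraries with carried-over tissue the log2 fold change with age in exercised fish turned to -0.41 for POMC, -0.41 for myhz1.1, -0.62 for myhz2, -2.31 for myhz1.2 and -0.0908 for prl, whose high values lay in those libraries. The covariance of exercise at 3 years with age without exercise, -0.0127, turned to 0.0583 with the shared libraries split between the effects, which removes the covariance they add. Leaving out a library gave 0 to 197 calls for exercise at 1 year, 3 to 7 at 3 years, 0 to 2 for the age difference, 89 to 434 for the averaged effect, 78 to 257 for age without exercise and 855 to 2247 for age with exercise, and rho of 0.101 to 0.403 for exercise and 0.434 to 0.579 for age. The share of higher calls moved in the averaged effect from 144 against 48 to 405 against 255 with DESeq2 and to 15 against 2 on the deposited RPKM, and for age without exercise from 47 against 77 to 288 against 271 without both libraries numbered 1. The deposited RPKM moved the median log2 fold change of all genes to 0.18 for exercise at 3 years, 0.21 for the age difference and 0.17 for age with exercise.

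Of 3950 values of named genes under the other alternatives, 3250 kept their direction and side of the threshold, 651 lost the call, 44 gained it and 5 reversed. Of 3010 with a library left out, 2412 kept both, 579 lost the call, 19 gained it and 0 reversed. Of 73 gene list results past the threshold, 55 stayed past it under the stricter filter. Thinning every library to 23.4 M counts, which lowers depth to that of the smallest library, gave 186, 123 and 2146 calls for the averaged effect and both age comparisons.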

Other observations

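The count of genes that separate the ages without a library was chosen after the results were seen. Genes named in the next paragraph come from the lists set in advance.

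Further genes that differed with age in exercised fish belong to lists with few calls. NDRG1 (ENSDARG00000010420), a gene that hypoxia induces, was higher at 3 years (log2 fold change 1.77 ± 0.40, adjusted p = 0.0125), while other hypoxia genes, SLC2A1 (ENSDARG00000001437), the glucose transporter of the blood-brain barrier (-0.42 ± 0.12), EPAS1 (ENSDARG00000057671) (-0.47 ± 0.14) and IGFBP1 (-1.51 ± 0.35), were lower. Of the glucocorticoid target list, NR3C1, the glucocorticoid receptor, was slightly higher (0.19 ± 0.05). NOTCH1 (ENSDARG00000103554), a receptor in the radial glia list, was higher (0.50 ± 0.09), as was MCM7, of the replicative helicase (1.16 ± 0.35). In the extracellular matrix list TNC (ENSDARG00000021948) (-0.60 ± 0.12) and BGN (ENSDARG00000017884) (-1.18 ± 0.37) were lower, and in the endothelial list FLT4, a receptor of lymphatic endothelium, was lower (-0.72 ± 0.22) and ESAM higher (0.50 ± 0.14). The antioxidant genes SOD2 (-0.24 ± 0.07) and GPX4 (-0.28 ± 0.08) were lower and GCLC, of glutathione synthesis, higher (0.23 ± 0.06). CHAC1, which breaks down glutathione, was lower (-0.59 ± 0.12) and DDIT3, a transcription factor of the same stress list, higher (0.34 ± 0.11). NTRK3 (ENSDARG00000086214), a neurotrophin receptor, was lower (-0.55 ± 0.16). These log2 fold changes had adjusted p of 0.00542 to 0.0481 in edgeR.

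One library lay with the other age at several genes. With unexercised 3-year replicate 1 left out, 13 genes separated the ages in the other libraries by at least 2-fold, and with any other library left out 3 or 4 did. At 9 of the 13 this library was on the side of the 1-year fish. A gene gained by leaving a library out has that library between the ages or on the other side, so it is the number of genes that sets this library apart.

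Some genes took separate levels within groups. otoa was at 2.19 CPM in unexercised 1-year replicate 5 and 4.12 CPM in exercised 1-year replicate 5, and between 115 and 251 CPM in the other 8 libraries of 1 year. In unexercised 3-year fish it was at 112, 118 and 274 CPM in 3 libraries and at 3.59 and 3.84 CPM in 2. mhc2dab was at 72.6, 124 and 322 CPM in 3 exercised 3-year libraries and at 4.2 and 5.26 CPM in the other 2.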
